A study of Mus musculus with 2 samples.

How the data were processed

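Single-cell RNA libraries were made from colon epithelium of wild-type C57BL/6 mice 2 weeks after irradiation (1 group, 2 libraries). Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 2.3 were used with the mouse build mm10 (GRCm38). The annotation, the filters on cells and genes, the treatment of doublets and the clustering settings are not given in the sources used here. The file the authors deposited holds 17044 gene symbols by 12 clusters. Its values are mean UMIs per 10000 on a linear scale: each cell was scaled to 10000 UMIs and averaged over the cells of a cluster, which was read from the values, since each column sums to 10000 and the low values are 10000 divided by whole numbers. No column names a library, so the cells of both libraries were taken to be pooled. Averaging hides how a level is spread over cells, and a few cells of another type can set the value of a gene that the rest lack.

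The arithmetic of the averages gave the depth. Where 1 cell has 1 UMI of a gene, 10000 divided by the average is the number of cells times that cell's UMI total, so it is whole. Values of 10000 divided by the average were called whole within a relative tolerance of 1e-12. The number of cells of a cluster was taken as the number that divides most of them, weighted by its logarithm. It divided from 90.3% to 100.0% of these values in each cluster, against at most 53.7% for any larger number. A cell's UMI total was accepted where at least 2 genes gave it. Totals were identified for 2299 of 3082 cells (74.6%), the lowest at 509 UMIs. An average was said to come from 1 cell where it equals a whole number of UMIs in 1 identified cell. Approximate UMI numbers behind an average were computed from the cells and the harmonic mean of the identified totals, with exact Poisson 95% intervals that cover counting error only. A value of 0 allows up to 3 UMIs.

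The steps were checked on simulated data. Cells were drawn for all 17044 genes from each cluster's real profile, with its recovered number of cells and its identified depths. The number of cells was recovered in all 12 clusters. Whether the cells without an identified total had other depths was not tested. All recovered totals were true ones, and the median recovered total lay between 0.96 and 1.25 times the simulated median. With 1 shared profile for the 12 clusters and 200 raised genes among the 17044, all 50 genes raised 4-fold, all 50 raised 8-fold and all 50 raised 16-fold were called as leading, and 1 of 50 raised 2-fold. The number of false leading genes was 0. This covers the sampling of UMIs only, since the simulated cells of a cluster were alike, with no cells of another type and no free RNA. In the same simulated table a list of 20 genes raised 2-fold lay above all 10000 random lists. An unchanged list of 20 lay at the 31.5 percentile. The clusters there shared 1 profile apart from the raised genes, and the list was raised directly in the averages. The result was therefore nearly fixed, and it does not check the percentiles of the real clusters, whose profiles differ.

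Because the file holds averages without replicates, no test, p-value or standard error was computed. The planned difference between libraries was not run, because the columns do not separate them. For each cluster the leading genes were those at 1 or more per 10000 and at least 2-fold above the highest other cluster, with a pseudocount of 0.1 per 10000, which understates the fold of low genes. Of 19 cell type lists and 20 program lists, those with at least 3 measured genes were scored. Their median log2 fold over the mean of the other clusters (same pseudocount) was compared with 10000 random lists of the same size, matched in 50 bins of mean expression. The reporter list had no measured gene and the fibroblast list had 2, so neither was scored. The percentile describes these averages and is not a p-value. A cluster was called like a cell type where at least 3 of its markers were detected and its leading genes did not go against the name. Names went to clusters whose highest cell type list lay above all 10000 random lists, a condition settled after the values were seen. A cluster with a median depth below 4081 UMIs, the overall median divided by 3, also needed a marker among its top 10 genes by fold. Cluster 6 was shallow by this measure and was left unnamed, as was cluster 10, where several lists stood out. Similarity was Spearman's rho across genes at 1 or more per 10000 in at least 1 cluster.

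Genes were named by a rule fixed in advance: per cluster the 3 with the largest fold over the highest other cluster and the 3 with the largest fold over the mean of the others, the 4 highest members of each list, and 14 genes set in advance. Outside this rule, Duox2, Krt14, Krt20, Ifit1, Gdf15, Edn1, Smoc2, Trpm5, Sh2d6, Ly6g, Rn7sk, Malat1, Retnla, Xist and the Y-linked genes were chosen after their values were seen. The same holds for Ang4, Retnlb, Lyz1, Gcg, Ppy, Reg3b, Reg3g, Areg, Nos2 and Lcn2. The text describes part of the genes that the rule names, picked after their values were seen. The other genes, and 1 program list, are not reported here. Of the 17044 symbols, 16392 (96.2%) were found in GENCODE M21, which gave the gene positions. Symbols are printed as in the file, some in older form. Alternatives covered the reference, minimum level, pseudocount, fold, scaling, list summary and left-out clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.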

Results

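The study measured single-cell transcriptomes of colon epithelium from wild-type C57BL/6 mice 2 weeks after irradiation. Its title places the samples in work on colonoids, organoids grown from colon crypts, transplanted into a rectum injured by radiation. There was 1 group with 2 libraries, and untreated, unirradiated or untransplanted samples were not analysed here. The labels do not say which cells descend from a graft. The values were the authors' averages of each gene over the cells of 12 clusters, numbered 0 to 11, in UMIs per 10000 UMIs of a cell. The columns name clusters and no library, so the cells of both libraries were taken to be pooled. No value has a replicate, no test between groups was possible, and differences between clusters are described by size, with 95% intervals that cover counting error only. The authors drew the clusters from the same expression values, so a cluster's distinguishing genes describe it and are not independent evidence.

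The arithmetic of the low values gave the number of cells behind each average. Together the clusters held 3082 cells, from 482 in cluster 0 down to 31 in cluster 10 and 19 in cluster 11. UMI totals could be read for 2299 of these cells, with a median of 12243 UMIs. By cluster the median ranged from 1430 UMIs in cluster 5 and 2505 in cluster 6 to 19522 in cluster 7. Clusters 5 and 6 lay below 4081 UMIs, the overall median divided by 3. The share of mitochondrially encoded RNA was 8.05% in cluster 6, the highest of the 12, and 0.923% in cluster 10, the lowest. Ribosomal protein genes took 22.8% of the RNA in cluster 2 and 22.8% in cluster 7, against 4.01% in cluster 8, 5.54% in cluster 5 and 5.87% in cluster 4.

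**Figure D1:**
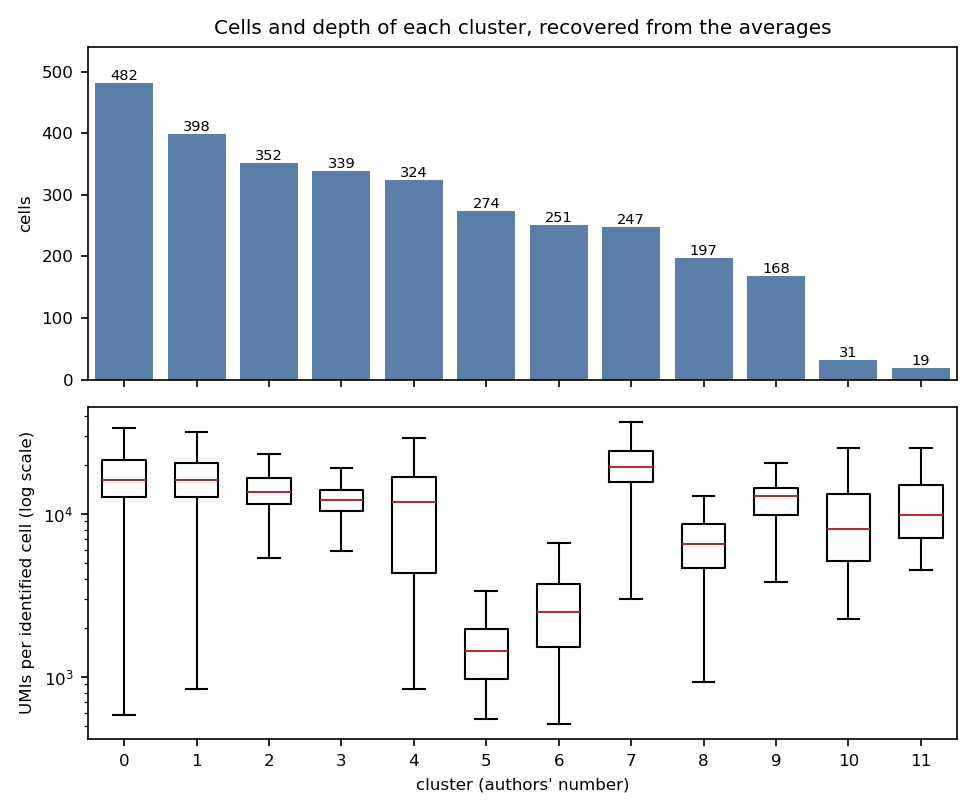
Top: number of cells in each of the authors' 12 clusters, recovered from the averages. Bottom: UMIs per cell (log scale) for the cells whose total could be read, with boxes from the lower to the upper quartile, the median in red and whiskers to the last value within 1.5 box lengths; clusters 5 and 6 have the lowest medians, 1430 and 2505 UMIs.

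The first question was which cell types the clusters hold, read from marker lists fixed before the data were examined. Cluster 0 was goblet-like: 18 of the 20 goblet markers had their highest value there, with a list median 4.28 log2 units above the mean of the other clusters. Mucus and goblet secretory genes led it, among them Zg16, a lectin of the mucus layer, at 157.6 per 10000 (95% interval 156.5 to 158.8), Tff3 at 218 and Muc2, the main gel-forming mucin, at 79.2. Of the 8 deep crypt secretory markers, 7 were also highest in cluster 0, including Reg4 at 47.9 and Mptx1 at 207. Cluster 11 was enteroendocrine-like, with all 17 measured markers highest there and a list median of 5.25. Its 19 cells averaged 842 per 10000 of Pyy (829 to 856), which encodes peptide YY, 148 of Chgb, 107 of Sst (somatostatin) and 47.4 of Insl5. Cluster 7 was proliferating-like, with 22 of 22 cycle markers highest there, a list median of 2.55, and Stmn1 at 7.25, Birc5 at 3.67 and Cdk1 at 1.59 per 10000. Cluster 5 was neutrophil-like despite its shallow cells: 7 of 8 neutrophil markers were highest there, with S100a9 at 442 (435 to 449), S100a8 at 427 and Retnlg at 31.4. The remaining neutrophil marker, Ly6g, stood at 0.603 in cluster 5 and at 8.19 in the epithelial cluster 8. Clusters 8 and 9 were absorptive colonocyte-like, with 9 and 7 of 25 markers highest and list medians of 1.77 and 0.75. Cluster 4, left unnamed, also had 7 of the 25 highest, with 8 at least 2-fold higher, 6 at least 2-fold lower and a median of -0.06, and it was about as close to cluster 8 (Spearman's rho 0.91) as to cluster 1 (0.90). By the naming rule, each list median that gave a name lay above those of all 10000 random lists of like size and expression. That condition was settled after the values were seen, so it adds no support for the names. With a pseudocount of 1 the medians were lower, at 2.57 for goblet, 2.84 for endocrine, 1.14 for cycle and 2.97 for neutrophil markers.

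Cluster 10 joined several immune types in 31 cells and was left unnamed. There 12 of 15 macrophage and dendritic markers, 11 of 12 T and NK markers and 6 of 8 mast cell markers had their highest value, and all 7 class II genes stood highest, with a median of 7.89 log2 units above the other clusters. Cd74, the class II invariant chain, was at 216 per 10000, Mcpt1, a mucosal mast cell protease, at 126, Apoe at 47.2, Ccl5 at 9.64 and Cd3g at 1.17. Of its leading genes, 2 each came from UMIs of 1 cell, among them Retnla at 12.8. Ptprc, the pan-leukocyte gene, was at 3.69 in cluster 5 and 1.78 in cluster 10, and Epcam ranged from 14.9 in cluster 11 to 37.6 in cluster 4 among the epithelial clusters, against 3.83 in cluster 5 and 2.89 in cluster 10. The muscle, endothelial and red blood cell lists gave little signal in any cluster. Of 13 fibroblast markers, 2 were analysed here, too few for a list median, with Vim reaching 4.76 in cluster 10 and Mgp at most 0.0506. The endothelial median was highest in cluster 10 at 0.17 and that of muscle and pericytes in cluster 1 at 0.02, and red blood cell markers reached at most 0.0828 per 10000 (Hba-a2 in cluster 11). The 4 glial and neuronal markers measured had a median of 1.25 in cluster 11, where Tubb3 was at 0.908. Clusters 1, 2, 3, 4 and 6 had no cell type list that named them and are given by number.

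**Figure D2:**
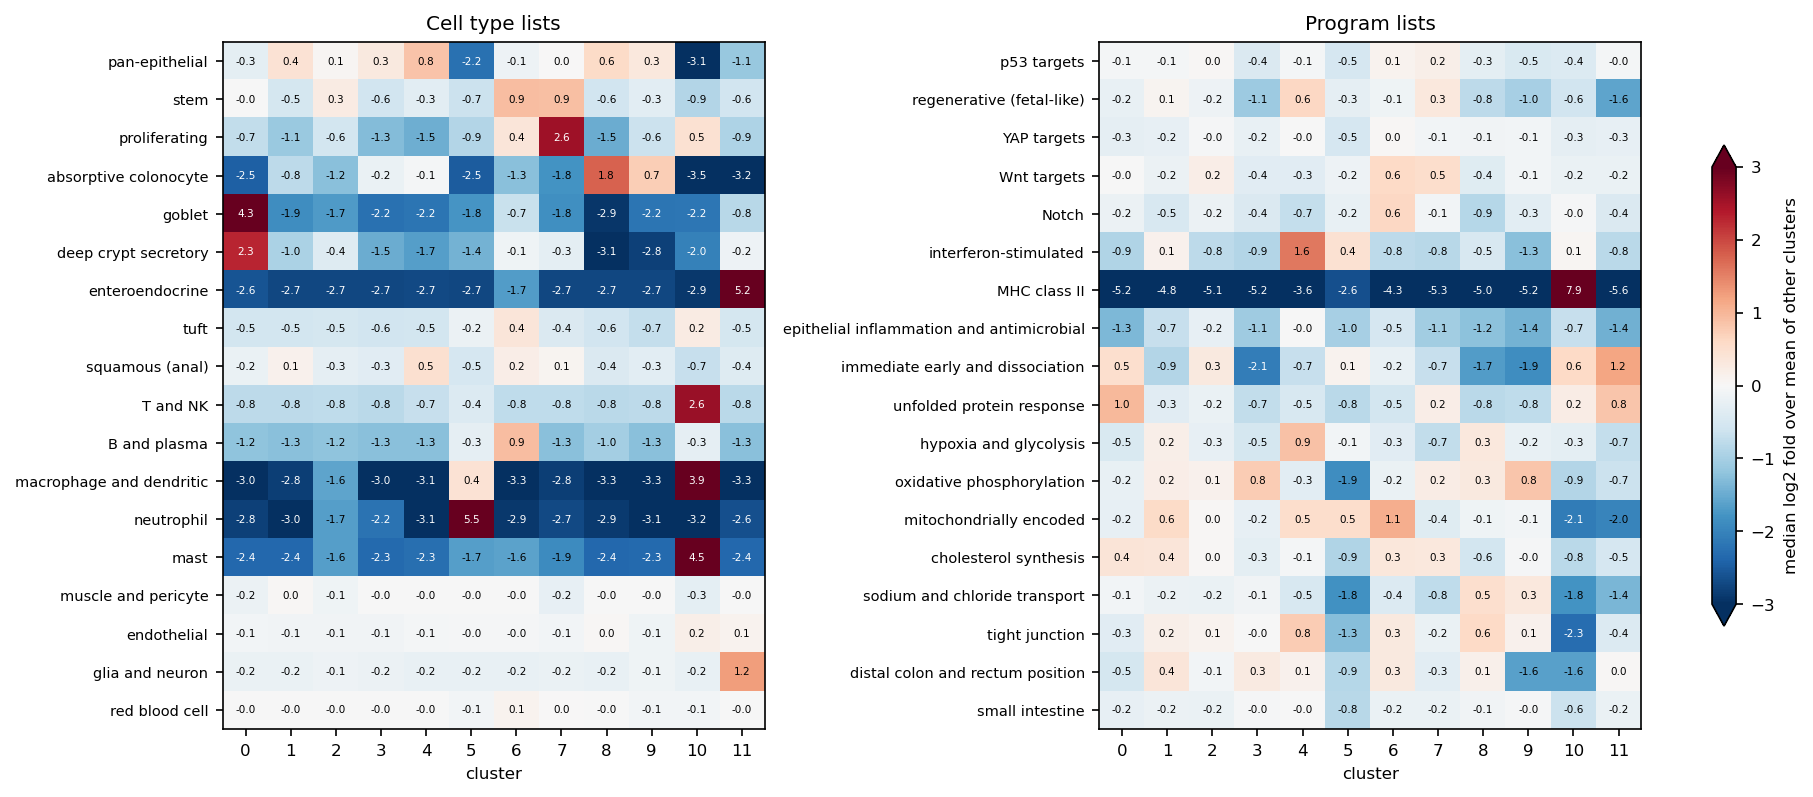
Median log2 fold of fixed gene lists in each cluster (columns) over the mean of the other clusters, for cell type lists (left) and program lists (right), with colours cut at 3 in both directions and values printed in the cells. Goblet markers stand out in cluster 0 (4.28), endocrine markers in cluster 11 (5.25), and interferon-stimulated genes in cluster 4 (1.58).

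Cluster 4 (324 cells) had the highest values of Clu and Ly6a, genes linked to injury of the gut, and the highest interferon median of the 12 clusters. Clu, a marker of revival cells in injured gut, was at 23.6 per 10000 there (22.8 to 24.3) and at 14.5 in cluster 1 (14.1 to 14.95), against 3.24 in cluster 2 and 0.242 in cluster 0. Ly6a (Sca-1), a gene of fetal-like repair states, was at 27.3 in cluster 4 (26.5 to 28.1) and 10.7 in cluster 1, against 9.56 in cluster 8 and 1.90 in cluster 2. Of the 20 regenerative genes, 8 were highest in cluster 4 and 7 lay at least 2-fold above the mean of the others, with a list median of 0.63 (0.28 with a pseudocount of 1), above all 10000 random lists. The same list had medians of 0.32 in cluster 7, with 4 members highest there, and 0.08 in cluster 1, with 0 highest. In clusters 3 and 9 its medians were -1.10 and -1.01. These 2 shrank to as little as -0.30 and -0.36 under the alternatives. S100a6 stood at 158 in cluster 4 and Anxa1 at 6.91. In the same cluster mitochondrially encoded RNA took 6.55%, Malat1 4.76% and ribosomal protein genes 5.87% of the RNA, and the lower quartile of UMIs per cell was 4310.

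Interferon-stimulated genes stood higher in cluster 4 as well: 16 of 20 were at least 2-fold above the mean of the other clusters, with a list median of 1.58 (0.54 with a pseudocount of 1). Irf7, an interferon regulator, was at 7.09 there (6.69 to 7.50) against 2.08 in cluster 1, and Ifit1 at 1.54. Isg15 was at 5.43 in cluster 4 but higher in the neutrophil-like cluster 5, at 12.6. Duoxa2, the maturation factor of the dual oxidase that releases hydrogen peroxide at the mucosal surface, was at 8.89 in cluster 4 (8.44 to 9.35) and 1.39 in cluster 1. Duox2, the oxidase itself, was at 4.96 and 0.949. Ly6d, at 2.40, and Clca4b, at 5.25, were also highest in cluster 4. Of the hypoxia and glycolysis genes 8 of 16 were highest in cluster 4, and 7 were at least 2-fold above the mean of the others, with a median of 0.89 (0.42 with a pseudocount of 1) and Hk2 at 3.67. Of the tight junction genes 4 of 14 were highest in cluster 4 and 4 in cluster 8, with medians of 0.77 and 0.60 (0.40 and 0.13 by the mean over the list's genes), and Cldn7 was at 26.8 and 24.2. The squamous (anal) list had a median of 0.49 in cluster 4, with Sfn at 12.04 and Sprr1a at 1.71, while Krt14 was at 0.415 and Krt5 was not analysed here. Krt20, a marker of mature surface cells, was at 12.2 in cluster 4, 10.8 in cluster 8 and 7.19 in cluster 9, and Lypd8, an antibacterial surface protein, at 485, 369 and 78.2. The epithelial inflammation list as a whole had a median of -0.02 in cluster 4. Xist, the RNA of the inactive X chromosome, was at 2.99 in cluster 4 and listed at 0 in cluster 8, with the same shares of mitochondrially encoded RNA and Malat1 in cluster 4 as above.

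**Figure D3:**
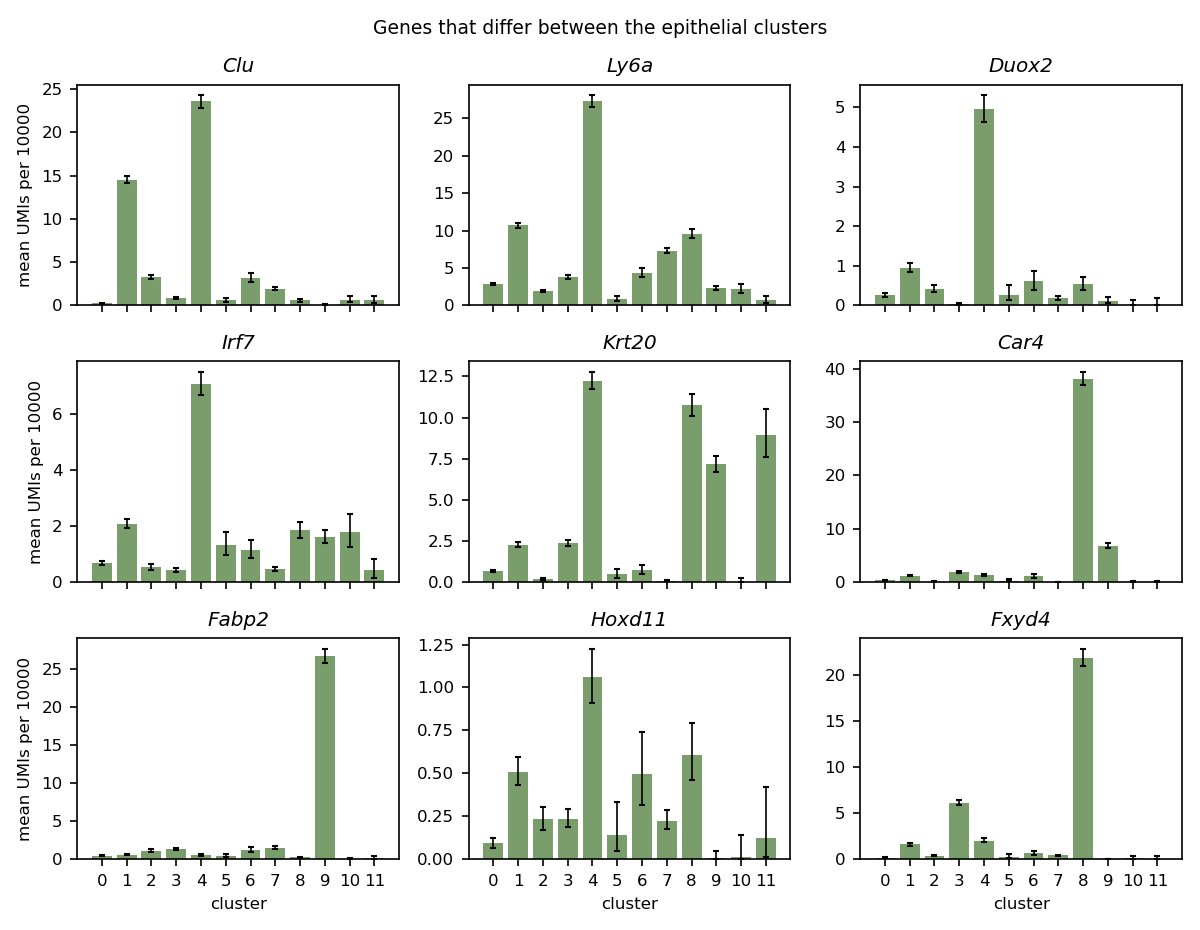
Mean UMIs per 10000 (vertical axes, each from 0) of 9 genes in the 12 clusters, with bars for the authors' averages and error bars for 95% Poisson intervals that cover counting error only. Clu and Ly6a are highest in cluster 4 (23.6 and 27.3), Car4 and Fxyd4 in cluster 8 (38.1 and 21.9) and Fabp2 in cluster 9 (26.7).

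Several absorptive and position genes differed between the absorptive clusters 8 and 9. Cluster 8 led in Car4, a surface carbonic anhydrase, at 38.1 (36.9 to 39.4) against 6.82 in cluster 9, and in Aqp8 (23.3 against 4.45), the chloride exchanger Slc26a3 (20.7 against 4.33) and Saa1 (168 against 14.2). Cluster 9 led in Fabp2, the intestinal fatty acid binding protein, at 26.7 (25.8 to 27.7) against 0.212 in cluster 8 (0.131 to 0.332). Car1 was high in both, at 74.4 in cluster 8 and 60.4 in cluster 9, and Guca2a was at 78.0 and 149.7. Oxidative phosphorylation genes had medians of 0.83 in cluster 9 and 0.75 in cluster 3, with Cox4i1 at 41.1 and 49.7. Xist was listed at 0 in cluster 8 and at 0.0223 in cluster 9, from 1 cell, against 1.34 in cluster 1. Sodium and chloride transport genes went both ways in cluster 8, with 6 of 15 at least 2-fold higher and 4 at least 2-fold lower than the mean of the others (median 0.50), as in cluster 9, with 3 higher and 3 lower (median 0.31).

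Part of the genes of the distal colon and rectum were low in cluster 9. The list of 9 measured genes had a median of -1.63 (-0.28 with a pseudocount of 1), below all 10000 random lists with the pseudocount of 0.1, with 5 of 9 at least 2-fold lower and a bootstrap interval over genes of -2.03 to 0.19, which includes 0. Fxyd4, a regulator of the sodium pump, was at 0.0162 in cluster 9 (0.00203 to 0.0606) against 21.9 in cluster 8 and 6.11 in cluster 3. Hoxd11 was at 0.00782 in cluster 9 (0.000212 to 0.0467) against 0.607 in cluster 8 (0.463 to 0.793), and Hoxb13 at 1.31 against 7.72. Among the members that were not lower, Hoxa11os was at 0.959 in cluster 9 and 0.791 in cluster 8. The small intestine list stayed near 0 in cluster 9, with a median of -0.03, and its paneth cell defensin Defa24 was found in cluster 0 at 1.90.

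Cluster 3 (339 cells) was close to cluster 9, with a rank correlation of 0.94, and to cluster 1, with 0.93. Gsdmc3 was its leading epithelial gene at 1.77, against 0.713 in cluster 9. Its largest folds belonged to the neutrophil granule genes Ngp, at 2.81, and Camp, at 2.35, and the Ngp value came from UMIs of 1 cell. Immediate early and dissociation genes were low in clusters 3, 8 and 9, with medians of -2.08, -1.69 and -1.86, and high in cluster 11, with 1.19. Fos, for example, was at 5.25, 6.73 and 5.57 in the first 3 and at 36.6 in cluster 11.

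Stem cell genes were highest in clusters 6 and 7. The list of 15 had medians of 0.93 (0.25 with a pseudocount of 1) and 0.91, both above all 10000 random lists. In cluster 2 the median was 0.26 (0.04 to 0.51 under the alternatives). Lgr5, the marker of crypt base stem cells, was scarce everywhere: 0.115 per 10000 in cluster 7 (0.0800 to 0.163), 0.117 in cluster 6 from about 5 UMIs (0.0348 to 0.250), 0.0328 in cluster 2 and listed at 0 in cluster 3, where up to 0.00918 would be allowed by 3 UMIs. Smoc2 was at 1.10 in cluster 7 and 0.704 in cluster 2, and Slc12a2 at 2.18 in cluster 6 and 1.58 in cluster 7. Wnt target medians were 0.60 in cluster 6, 0.52 in cluster 7 and 0.19 in cluster 2 (0.11, 0.10 and 0.03 with a pseudocount of 1), with Ccnd1 at 1.37 in cluster 6. Notch genes had their highest median in cluster 6 (0.63, and 0.14 with a pseudocount of 1), although none of the 9 measured was highest there, and Hes1 was at 3.90 in cluster 2 and 3.40 in cluster 6. Mki67, a marker of cycling cells, was at 1.47 in cluster 7 and 0.726 in cluster 6.

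Cluster 6 (251 cells, median 2505 UMIs) also held transcripts of other types. Its largest folds were immunoglobulin genes, with Igkc at 13.8, Igha at 9.41 and Jchain at 3.16 per 10000. The tuft cell gene Dclk1 was at 1.12 (0.832 to 1.46) against at most 0.0247 elsewhere, Trpm5 at 0.510 and Sh2d6 at 0.532. Rn7sk, a nuclear RNA, was at 11.9 per 10000 against 1.98 in cluster 0, while Malat1, at 4.85% of the RNA, was close to its 4.76% in cluster 4 and 3.79% in cluster 1. B and plasma cell markers had a median of 0.92 and tuft markers of 0.37. The mast cell genes Mcpt1 and Mcpt2, at 3.01 and 1.11, each came from 1 cell of cluster 6.

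Cluster 2 (352 cells) was led by 3 genes, and by 0 with a pseudocount of 1 or at 4-fold. Edn2 (endothelin 2) was at 1.70 per 10000 (1.54 to 1.89) against 0.628 in cluster 7, and Hbegf, an EGF receptor ligand, at 8.90 (8.51 to 9.30) against 4.03 in cluster 1. The uncharacterised 8430408G22Rik was at 1.13 against 0.448 in cluster 7. Edn1 at 3.18 and Gdf15 at 1.68 were also highest there, at 1.61-fold and 1.74-fold over the next cluster, under the 2-fold rule. The same cluster had the highest median of neutrophil markers of the epithelial clusters, with S100a8 at 16.2 and S100a9 at 15.5, against 0.526 and 0.171 in cluster 4. These were 3.80% and 3.51% of their level in cluster 5, against 1.64% and 1.24% in cluster 3. Lcn2 was higher in cluster 3, at 10.5% against 0.230% in cluster 2. Cxcl2, a chemokine outside the neutrophil list, was at 17.0 in cluster 2, 0.633 in cluster 4 and 36.5 in cluster 10. Cluster 1 (398 cells) had no gene 2-fold over the highest other cluster, and Clu was its largest gene by fold over the mean of the others, at 4.39-fold.

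Genes of the p53 response, which radiation can induce, showed no cluster with a high list median: it ranged from -0.51 in cluster 5 to 0.17 in cluster 7. Against random lists the low medians were those of clusters 3 and 9, at -0.43 and -0.45 (percentiles 0.13 and 0.06). They shrank to as little as -0.11 and -0.09 under the alternatives. The bootstrap interval over genes was -0.68 to 0.02 in cluster 3, which includes 0, and -0.61 to -0.25 in cluster 9. Cluster 5 lay at the 65.0 percentile. Each median is relative to the other clusters, all from irradiated mice, so a response shared by all clusters would not show. Cdkn1a, the p21 cell cycle inhibitor, was at 6.52 in cluster 8 (6.01 to 7.06), 6.11 in cluster 4 and 1.11 in the proliferating-like cluster 7 (0.991 to 1.24), and Btg2 was at 13.9 in cluster 5 and 1.74 in cluster 9. YAP target medians ran from -0.51 in cluster 5 to 0.04 in cluster 6, with Cyr61 at 3.59 in cluster 0. Unfolded protein response genes had medians of 0.98 in cluster 0 and 0.83 in cluster 11, with Hspa5 (BiP) at 9.72 and 13.3. Cholesterol synthesis medians were 0.39 in cluster 0 and 0.35 in cluster 1 (0.17 and 0.16 at the lowest under the alternatives). Fdps was at 1.84 and 1.78 there, below its 2.54 in cluster 7. The mitochondrially encoded list had its highest median, 1.09, in cluster 6. Neither the 8 reporter names looked up nor a graft label were analysed here.

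Over all clusters, 767 genes were at least 2-fold above the highest other cluster and at 1 or more per 10000, and over the mean of the others there were 2679 such pairs of gene and cluster. Most of the 767 led cluster 5 (247), cluster 11 (196) or cluster 10 (122), and among the others cluster 0 had 69, cluster 8 had 39, cluster 7 had 34, cluster 4 had 29, cluster 9 had 16, cluster 6 had 9, and clusters 2 and 3 had 3 each. Of the 767, 4 rested on UMIs of 1 cell. Of 228 pairs of program list and cluster, 39 lay above and 66 below the central 95% of random lists, where 11.4 would lie outside by chance for lists of independent genes, which genes of one pathway are not. Across 3276 genes, Spearman's rho between clusters had a median of 0.68 over 66 pairs, from 0.29 to 0.94. Genes are not independent replicates, and no p-value was computed.

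Positions on GRCm38, 1-based, were as follows for the genes that carry most of these comparisons. Clu lies on chromosome 14 from 65968483 to 65981547 and Ly6a on chromosome 15 from 74994877 to 74998031. Duox2 lies on chromosome 2 from 122279247 to 122298449 and Fabp2 on chromosome 3 from 122895072 to 122899506. Car4 spans 84957786 to 84966044 on chromosome 11, and Lgr5 spans 115450311 to 115587780 on chromosome 10. All 6 are annotated as protein-coding.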

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

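Alternatives that leave out a gene from 1 cell, a whole cluster, or for cell type lists the ribosomal protein and mitochondrial genes were chosen after seeing the data. The others were set in advance. The 767 leading genes became 2679 with the mean of the other clusters as reference and 3488 with their median, both counted as pairs of gene and cluster and both including all 767. They became 1208 with a minimum of 0.5, 446 with a minimum of 2 and 1976 with none, 465 with a pseudocount of 1, and 383 at 4-fold, which follow from a looser or stricter criterion. The other settings moved this total by less than 1.5 times: 813 with a pseudocount of 0.01, 816 after rescaling without ribosomal protein and mitochondrial genes (703 shared), 778 to 927 with each cluster left out of the reference, 763 without genes from 1 cell, 775 without cluster 6 and 637 without clusters 10 and 11. Counts of single clusters moved more: of 285 recomputed, 211 stayed within 1.5 times and 74 did not, with cluster 4 from 8 to 412, cluster 2 from 0 to 115 and cluster 1 from 0 to 118. The median rho between clusters was 0.68, 0.84 with all detected genes and 0.73 as Pearson's r of log2 values, and the cause was not tested.

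A cell type list reached a median of 1 log2 unit in 6 clusters, and in 5 to 9 under the alternatives. The program pairs outside the central 95% numbered 105, and 92 to 112 under them. Rescaling shifted the median of all genes by between -0.18 (cluster 8) and 0.15 log2 units (cluster 2), and by -0.13 in cluster 4. The interferon median of cluster 4 was then 1.61 and its regenerative median 0.56. Over all alternatives the interferon median ran from 0.54 (pseudocount 1) to 2.16 (without clusters 5, 10 and 11), the regenerative median from 0.28 to 1.01, and the distal median of cluster 9 from -2.27 to -0.28. The stem median of cluster 6 ran from 0.25 to 1.49, both ends set by the pseudocount, as were those of the Wnt medians of cluster 6 (0.11 to 1.68), 7 (0.10 to 0.98) and 2 (0.03 to 0.45) and of the Notch median of cluster 6 (0.14 to 0.96). Program medians were recomputed for a chosen part of the 228 pairs of list and cluster. Of 332 recomputed values 294 stayed within the bootstrap interval of the list, 38 moved, and 0 reversed from a median of at least 1 log2 unit. Changes of sign in smaller medians were not counted as reversed, and the YAP median of cluster 4, for example, ran from -0.04 to 0.26. Leaving out either library was not run, because the columns do not separate them. No paired analysis was possible because there is 1 group and no library columns. Shallow clusters 5 and 6 and the 31 and 19 cells of clusters 10 and 11 limit precision: 3 UMIs are worth 0.0852, 0.0643, 0.139 and 0.174 per 10000 there, against 0.00641 in cluster 0.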

Other observations

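All tests below were chosen only after the patterns were seen.

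The secretory clusters held further detail. Ang4, an antimicrobial ribonuclease, was at 5.33 per 10000 in the goblet-like cluster 0 and at most 0.190 elsewhere, Retnlb was at 3.62 there, and Lyz1, a paneth cell lysozyme, at 0.842. In the 19 endocrine-like cells, Gcg (glucagon) was at 20.5 and Ppy (pancreatic polypeptide) at 55.2, beside Pyy at 842. The lectins Reg3b and Reg3g stood highest in the proliferating-like cluster 7, at 0.606 and 0.879, and not in the Clu-rich cluster 4, at 0.00812 and 0.0203. Areg, an EGF receptor ligand, was at 5.58 in cluster 4, 4.03 in cluster 1 and 3.996 in cluster 2. Nos2, the inducible nitric oxide synthase, was at 0.864 in cluster 4, against 0.158 in cluster 6, the next epithelial cluster.

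Xist differed between the epithelial clusters: 2.99 per 10000 in cluster 4, 2.68 in cluster 6, 2.10 in cluster 7 and 1.34 in cluster 1, but 0.0197 in cluster 3, 0.0223 in cluster 9 (from 1 cell) and 0 in cluster 8, the 3 clusters with the lowest immediate early medians. Clusters 2 and 0 lay between, at 0.864 and 0.236. In cluster 0 the low Xist did not go with a low immediate early median (0.21 to 0.95 under the alternatives). Free RNA spread evenly over the cells of both libraries, as the only source of Xist, would give the clusters like values. The differences themselves already go against that, so this was no separate test. The 0 in cluster 8 allows an even background of at most 0.0322 (3 UMIs), and a smaller one is not excluded. The mean over all cells was 1.09. Free RNA of 1 library cannot be judged, because the columns pool the libraries. Of the values of clusters 1, 4, 6 and 7, 0 came from 1 cell. Cells of female and male animals in uneven shares may be the cause, and Xist together with 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d, Uty) in one pool leave room for such a mixture, but rho between Xist and the Y-linked sum was only -0.22 over the 9 epithelial clusters other than 11, too few to decide. The Y-linked sum of clusters 1, 4, 6 and 7 was 0.897 times that of clusters 3, 8 and 9 (0.759 to 1.06, counting error only). This speaks against a female majority over clusters 1, 4, 6 and 7 together only if cell types express Y-linked genes alike, which was not tested. Within them the sum ran from 0.580 in cluster 7 to 1.19 in cluster 6. Whether animals, graft and host, or libraries contribute differently to these clusters stays open, and with it how much of the contrast between cluster 4 and clusters 8 and 9 is one of cell state.

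Cluster 6 combined stem, immunoglobulin and tuft transcripts. Its identified cells had 0.185 times the median depth of the other 8 epithelial clusters (11 aside), with the highest mitochondrial share (8.05%). These cells were shallow and may be damaged. Both values had been seen before, so they do not test whether shallow or damaged cells explain the mixture. The endocrine markers stood at a median of 1.71% of their level in cluster 11, against at most 0.0204% in any other epithelial cluster (Pyy 18.0, Insl5 0.810), so a few cells of other types may be part of the cluster too. Goblet markers stood at a median of 6.88% of their level in cluster 0. They stood at 7.31% in cluster 11 and at most 3.28% in the other epithelial clusters. The summed Igkc, 0.346 of 1 cell's RNA, could come from few cells. Both explanations can hold together, and how many of its 251 cells are stem-like stays open.

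Neutrophil transcripts in cluster 2 stood at a median of 2.27% of cluster 5 over the 7 neutrophil markers at 1 or more per 10000 there, against 1.24% in cluster 3, 1.18% in cluster 11 and at most 0.340% in the other epithelial clusters. Free RNA spread evenly over the cells of both libraries is argued against by 0.119% in the shallow cluster 6. Free RNA of 1 library cannot be judged, because the share of each library in a cluster is unknown. Neutrophils among the cells of cluster 2, doublets with them, or transcription by the epithelial cells themselves were not told apart. In cluster 3 the granule genes Ngp, Camp and Lcn2 (0.699) stood out instead, with Ngp from 1 cell.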
